A study of Mus musculus with 9 samples.

How the data were processed

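RNA was measured in 9 libraries of mouse CAFs (strain C57BL/6, KPC genotype): untreated controls and cells given 100 nM triptolide for 6 h or 24 h, with isolates 1, 5 and 7 in each group. Per the labels' protocols, cells were grown in medium with serum, RNA was extracted with a column kit and enriched for polyadenylated RNA, and libraries were sequenced as paired-end reads on an Illumina HiSeq instrument. The deposited table gave FPKM (fragments per kilobase of transcript scaled to the mapped fragments of the library), which the authors computed, with a column per library and no pooled values; the unit comes from the name of the deposited table and from its values. The submitters' processing notes name TopHat2 2.0.5, TopHat, Cufflinks 2.2.0 and Cuffdiff and the builds mm10 and GRCm38. The gene annotation, the filters, the strand setting and whether Cuffdiff rescaled the libraries are not given in the sources used here. Without a known strand setting, a gene and its antisense or overlapping partner cannot be told apart, and rows of near-identical copies are uncertain.

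The table had 44064 rows. Left out were 7029 rows without a gene name and 25 with a date in place of a symbol. Rows sharing a symbol (490 symbols) were summed, which gave 36469 symbols or loci, and 1771 rows naming more than 1 gene were kept as they were. Of the single symbols, 31987 were paired with GENCODE release M21 (build GRCm38), 1535 more through a RefSeq synonym, and 1152 were not paired. Coordinates are those of GRCm38 from GENCODE. An FPKM of 0 can be a failed estimate, so such values are called listed at 0 and are given per library: 185 tested rows were listed at 0 in a whole group and at a mean of 10 FPKM or more in another, and limma called 2, 21 and 7 of them at 6 h, at 24 h and between the times. Read totals were not given, so relative depth was taken from the step between the lowest FPKM values of the same genes, and no counting intervals could be given.

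Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), for 11924 genes with a mean of at least 1 FPKM over all 9 libraries. Each group had its own mean, all 9 libraries shared the spread (6 residual degrees of freedom), moderation followed the mean-variance trend, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Log2 changes are on the log2(FPKM + 1) scale and understate changes of low genes. Gene lists (43 lists of pathways, complexes and cell type markers, 37 of them with at least 5 measured members) were tested with camera, 111 tests in all, at a preset correlation of 0.01 and adjusted together; 23 passed, and 0 passed with an estimated correlation (22 and 0 with the isolate as a block). The design, the lists, 25 alternatives and 22 genes were fixed before the data were examined, and 4 alternatives and a simulation that keeps the isolate effects were added after. By the rule fixed then, the text names the 8 largest rises and falls (5 and 5 for 24 h against 6 h) among called genes with a single symbol that moved the same way in all 3 isolates. It also names up to 4 called members of each list described, those with the largest changes, or the 2 with the highest mean FPKM if fewer than 2 were called. Some of these are left out for brevity, and genes outside the rule are said to be chosen after their values were seen.

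The isolate numbers come from the labels and pair the libraries of the same preparation. Deviations from the group means correlated between libraries of the same isolate at 0.147 to 0.303 for isolate 1, 0.438 to 0.548 for isolate 5 and 0.137 to 0.287 for isolate 7. Between isolates 1 and 7 of different groups they correlated at 0.193 to 0.267, and between isolate 5 and the others at -0.415 to -0.244, so these values set isolate 5 apart and do not tell isolates 1 and 7 from each other. The fit with the isolate as a block was an alternative, because the tools named by the submitters take no block. The main fit thus leaves the pairing out, and differences between isolates enter its spread. A gene it did not call can still have moved the same way in every isolate. Other alternatives were the pseudocount, the filter, 4 scalings, the moderation, 2 groups only and leaving out each library or isolate; those added after were protein-coding rows only, rows sharing a symbol kept apart, rows listed at 0 left out, and the block on isolates 1 and 7 only. Ribosomal protein scaling set the median of 58 ribosomal protein genes equal in all libraries.

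The fits were tested on simulated data with 100 genes changed at each size among 11924, seed 20. At a log2 change of 1 the share recovered was 30% (6 h), 34% (24 h) and 25% (24 h against 6 h), and at a log2 change of 2 it was 74%, 77% and 77%, with 5, 6 and 4 false calls. These data had independent noise, no isolate effects and few changed genes, whereas limma called 6004 of the 11924 measured genes at 24 h. The shares therefore check the fits and do not give the recovery in the measured libraries. Shared controls were simulated 100 times with unchanged groups. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.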

Results

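Cancer-associated fibroblasts (CAFs), cells of the connective tissue that surrounds a tumour, had been isolated from pancreatic tumours of KPC mice. These mice carry mutant Kras and Trp53 and a Cre recombinase under the Pdx1 promoter and develop pancreatic cancer. Triptolide, a compound of the plant Tripterygium wilfordii, binds XPB, the ATPase of the general transcription factor TFIIH that the gene Ercc3 encodes, and blocks transcription by RNA polymerase II. The cells were left untreated or were given 100 nM triptolide for 6 h or 24 h, and polyadenylated RNA was sequenced. The 9 libraries fell into 3 groups of 3, with the CAF preparations numbered 1, 5 and 7 (called isolates here) present once in each group. Values below are mean FPKM ± SD (n = 3 libraries per group) unless stated otherwise.

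The FPKM of all rows summed to 680500 ± 21829 per control library, 997880 ± 54901 at 6 h and 1147400 ± 33375 at 24 h. Read totals were not given in the sources used here, but the spacing of the lowest values put the relative depth at 0.914 to 1.10 in the controls (isolate 7 set to 1), 1.05 to 1.2 at 6 h and 1.08 to 1.19 at 24 h. The microRNA precursor rows Mmu-mir-6236 (chromosome 9, 110281287 to 110281409) and Mmu-mir-6240 (chromosome 5, 114851948 to 114852064) held 11.2% ± 2.21 of the FPKM sum in the controls, 31.5% ± 2.62 at 6 h and 33.6% ± 1.67 at 24 h. FPKM divides by transcript length, so for rows this short a share of the FPKM sum is not a share of the fragments. The share of rows above 0 was 46.9% ± 3.07, 55.8% ± 2.03 and 62.3% ± 1.09. The median of all 11924 tested genes was itself shifted, by -0.11 (log2) at 6 h and -0.46 at 24 h against control and by -0.26 at 24 h against 6 h. The shift depended on the scaling. At 6 h and 24 h against control it was 0.004 and -0.13 with median-of-ratios scaling and 0.05 and 0.01 with upper-quartile scaling. With quantile normalization it was 0.05 and -0.06, and with ribosomal protein scaling -0.49 and -1.42. Changes of gene groups are therefore given relative to the median of the tested genes as well. FPKM is scaled to the library, so rises and falls below are relative to the other transcripts. The amount of RNA per cell was not measured.

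The control cells expressed Vim (1789 ± 593 FPKM), an intermediate filament gene of mesenchymal cells, and S100a4 (875 ± 473), together with the keratin genes Krt8 (593 ± 268), Krt18 (724 ± 26.2) and Krt19 (107 ± 21.4), which mark epithelial and mesothelial cells. Msln, a mesothelial marker, stood at 105 ± 30.3 FPKM and the epithelial genes Krt20, Cdh1 and Epcam at 78.6 ± 28.3, 18.8 ± 10.8 and 0.335 ± 0.322. Col1a1, the main fibrillar collagen gene of fibroblasts, was near the floor in the controls (0.992 ± 0.232), as were Fap (0.0487 ± 0.0844), Thy1 (0.010 ± 0.0174) and Dcn (0.31 ± 0.0919), and Lum was listed at 0 in all 3 control libraries. Col1a2, Col3a1 and Pdgfrb were low as well (2.78, 0.7 and 1.15 FPKM). Other markers went the other way. The mesenchymal genes Fn1, Sparc, Twist1 and Prrx1 stood at 349 ± 237, 221 ± 147, 31.3 ± 6.47 and 23.9 ± 7.21 FPKM. The epithelial genes Cldn4 and Esrp1 were near the floor (0.267 ± 0.257 and 0.133 ± 0.191). The markers were thus mixed. High keratin and Msln values beside low Col1a1, Fap, Thy1, Dcn and Lum leave it in question whether the cells were fibroblasts, although Vim and S100a4 were high. The name CAF comes from the sample titles, and the identity of the cells was not tested. Isolate 5 stood apart from the others: Acta2, the smooth muscle actin of activated fibroblasts, measured 82.1, 0.865 and 76 FPKM in control isolates 1, 5 and 7. Bgn, a matrix proteoglycan gene, measured 1406, 7.27 and 1538, and the Y-linked genes Eif2s3y and Ddx3y measured 0.44, 27.9 and 0.84 and 0.536, 29.3 and 0.549, respectively. Over the 3 groups, limma called 4241 genes between isolates 5 and 1 (2317 higher and 1924 lower in isolate 5), and between isolates 7 and 1 it called 0, with 54 genes at an unadjusted p under 0.05. The replicates there were the control, 6 h and 24 h libraries of 1 preparation, so those p-values do not measure the spread between preparations. The markers in this paragraph were chosen after their values were seen, apart from Acta2, Col1a1, Fap and Fn1. The labels do not state whether the isolates came from separate mice, so p-values of the comparisons between treatments measure the spread between these 3 preparations, of which 1 and 7 were nearly alike.

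The first comparison asked which transcripts changed after 6 h of triptolide. Ctgf, a secreted matrix protein gene and a target of YAP and TGF-beta signalling (chromosome 10, 24595442 to 24598683), fell from 171 ± 89.8 to 21.5 ± 14 FPKM (log2 change -2.91, SE 0.535, adjusted p = 0.0148). Ccl2, a chemokine that attracts monocytes (chromosome 11, 82035571 to 82037453), fell from 142 ± 43.5 to 21 ± 11.9 (log2 change -2.78, adjusted p = 0.0136). Ankrd1, a further YAP target (chromosome 19, 36111961 to 36120099), fell from 201 ± 16.6 to 33 ± 10.4 (log2 change -2.62, adjusted p = 0.0035). The transcription factor gene Cebpb (log2 change -2.52), the MAP kinase phosphatase gene Dusp1 (-2.46), Yeats4 (-2.33), the hedgehog co-receptor gene Gas1 (-2.31) and the cell cycle inhibitor gene Cdkn2b (-2.3) completed the 8 largest falls, each lower in all 3 isolates.

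Of the 37 measured immediate-early and early response genes, which cells switch on within minutes of a stimulus, 18 fell and 1 rose at 6 h (21 and 2 adjusted over the list alone). Dusp1 fell from 50.3 ± 10.3 to 8.57 ± 3.1 FPKM, Klf6 from 82.8 ± 21.6 to 17.4 ± 3.44, Ier3 from 261 ± 27 to 58.3 ± 11.9 and Klf2 from 13.4 ± 5.98 to 2.09 ± 0.992. The gene that rose was Btg2, an antiproliferative gene, from 6.3 ± 1.74 to 12.8 ± 1.49 FPKM (adjusted p = 0.0325). The list's median lay at -1.05 (log2) relative to all genes. Its camera test gave an adjusted p of 8.93e-07 with the preset correlation, and adjusted p = 0.584 with an estimated correlation.

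Among 16 secreted growth factors, 8 fell and 0 rose (10 and 0 adjusted over the list alone; 14 and 0 with the isolate as a block). They included the neuregulin gene Nrg1 (18 ± 1.44 to 4.48 ± 1.05 FPKM), Bdnf (7.38 ± 0.693 to 1.54 ± 0.453), the epidermal growth factor receptor ligand gene Areg (68.5 ± 51.5 to 17.7 ± 1.47) and the activin subunit gene Inhba (73 ± 11.3 to 24.9 ± 4.19). The list's relative median was -0.90, with camera adjusted p = 7.96e-05 and adjusted p = 0.584 with an estimated correlation. Of 25 genes of the TGF-beta pathway and targets, 7 fell (9 adjusted over the list alone; 13 with the isolate as a block). They included Ctgf, Cdkn2b (54.3 ± 14.7 to 10.6 ± 4.75 FPKM), the inhibitor of differentiation gene Id3 (log2 change -1.52) and the signal transducer gene Smad2 (26.1 ± 1.1 to 8.5 ± 1.14). That list lay at -0.44 relative to all genes. The camera test gave adjusted p = 0.00456 with the preset correlation, and adjusted p = 0.584 with an estimated correlation. Of 21 secreted cytokines and inflammatory fibroblast genes, 3 fell (6 adjusted over the list alone; 10 with the isolate as a block). These were Ccl2, the hyaluronan synthase gene Has2 (8.16 ± 3.01 to 1.33 ± 0.588 FPKM) and the macrophage growth factor gene Csf1 (90.9 ± 19.9 to 37.5 ± 12.4). Its relative median was -1.03. By camera, adjusted p = 0.0269 with the preset correlation, and adjusted p = 0.584 with an estimated correlation.

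Of 188 zinc finger transcription factors (symbols Zfp plus digits), 41 fell and 3 rose at 6 h (63 and 4 adjusted over the list alone; 86 and 4 with the isolate as a block). Zfp68 fell from 19.5 ± 1.14 to 5.22 ± 0.974 FPKM, Zfp1 from 6.56 ± 1.38 to 1.27 ± 0.308, Zfp637 from 22.2 ± 2.06 to 6.3 ± 0.463 and Zfp90 from 5.32 ± 0.919 to 1.24 ± 0.831. The list lay at -0.49 relative to all genes. Its camera result was adjusted p = 3.25e-07 with the preset correlation, and adjusted p = 0.857 with an estimated correlation. Members of other lists fell without the list passing its test. The hedgehog genes Gas1, Ptch1 (6.4 ± 1.09 to 2.37 ± 0.833 FPKM) and Disp1 (log2 change -0.83) fell, 3 of 5 measured in the hedgehog pathway, also 3 adjusted over the list alone (camera adjusted p = 0.0641). Of 10 anti-apoptotic genes, Mcl1 (80.3 ± 20.7 to 26.9 ± 4.38 FPKM, adjusted p = 0.00713), Bcl2l1 (75.1 ± 7.02 to 35.9 ± 2.31) and Cflar (log2 change -0.74) fell and 0 rose, against 4 and 1 adjusted over the list alone (camera adjusted p = 0.24). In the unfolded protein response, 4 of 29 genes fell (5 adjusted over the list alone; 8 with the isolate as a block; camera adjusted p = 0.926), namely Ddit4 (log2 change -2.11), the transcription factor gene Atf4 (-1.74), Herpud1 (-1.52) and the chaperone gene Hspa5 (-0.75).

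The largest rises at 6 h included rows of short and non-coding RNAs. AY036118, annotated as a long non-coding RNA (chromosome 17, 39847113 to 39848035) inside a ribosomal RNA locus, rose from 68.5 ± 54.6 to 988 ± 19.3 FPKM (log2 change 4.1, adjusted p = 0.00357). Mmu-mir-6240 rose by a log2 change of 2.47 (adjusted p = 0.00513), the antisense transcript Gm15564 from 8.64 ± 4.15 to 54 ± 19.8 FPKM and Gm11774 from 0.201 ± 0.157 to 4.85 ± 1.34. Polr2a, which encodes the largest subunit of RNA polymerase II (chromosome 11, 69733997 to 69758637), rose from 50.9 ± 7.72 to 267 ± 114 FPKM (log2 change 2.3, SE 0.324, adjusted p = 0.00691). Gm25190, a microRNA gene, was listed at 0 in every control and 24 h library and at 644, 2016 and 699 FPKM in 6 h isolates 1, 5 and 7. Gm25134 and Gm7618 were listed at 0 in all controls and at 9.41, 19.6 and 17.8 and at 7.04, 7.15 and 3.4 FPKM, respectively, at 6 h.

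Cytosolic ribosomal proteins and nuclear-encoded oxidative phosphorylation lay above the median of all genes at 6 h, mostly with small changes. Of 58 cytosolic ribosomal proteins, 2 rose and 0 fell, Rps24 from 1903 ± 73.6 to 2812 ± 121 FPKM and Rpl9 from 801 ± 32 to 1137 ± 54.8. By limma, 0 passed adjusted over the list alone, 21 rose at an unadjusted p under 0.05, and 44 rose with the isolate as a block. The relative median was 0.53. With camera the list had adjusted p = 2.33e-15 with the preset correlation, and adjusted p = 0.777 with an estimated correlation. For 64 genes of nuclear-encoded oxidative phosphorylation it was 0.49 (camera adjusted p = 1.27e-10; adjusted p = 0.857 with an estimated correlation), with 1 rise, 0 adjusted over the list alone by limma, 10 at an unadjusted p under 0.05 and 36 with the block. Atp5b measured 626 ± 87.5 and 870.5 ± 204 FPKM (adjusted p = 0.237, 0.0141 with the block). In the oxidative stress response, the iron storage gene Fth1 rose (2155 ± 104 to 3087 ± 41 FPKM) and the haem oxygenase gene Hmox1 fell (58.5 ± 1.62 to 18.6 ± 1.15), 1 and 1 of 24 genes, against 0 and 1 adjusted over the list alone and 11 and 2 with the isolate as a block. The list lay at 0.49 relative to all genes. Under camera it had adjusted p = 0.00124 with the preset correlation, and adjusted p = 0.584 with an estimated correlation. With the libraries scaled to the ribosomal protein genes, the raw medians turned negative for nuclear-encoded oxidative phosphorylation (-0.03) and the oxidative stress response (-0.02). Other abundant genes shared much of the ribosomal protein shift at 6 h. The raw median was 0.287 in 142 protein-coding genes of nearest control FPKM, against 0.424 for 57 ribosomal protein genes.

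Proteasome subunits (29 measured, relative median 0.35) and replication-dependent histones (21 measured, 0.35) passed camera at 6 h (adjusted p = 0.00121 and 0.042; adjusted p = 0.857 and 0.964 with an estimated correlation). Limma called 0 members of either, also adjusted over the list alone, and 4 and 1 were higher at an unadjusted p under 0.05. The proteasome genes Psmb4 (314 ± 53.1 and 376 ± 79.2 FPKM) and Psma2 (306 ± 133 and 374 ± 128) were not distinguished, and that list's raw median turned to -0.16 under ribosomal protein scaling. With the isolate as a block, 8 proteasome genes rose and 1 fell, and 2 histone genes rose and 1 fell.

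At 6 h limma called 1279 of 11924 genes, 196 higher and 1083 lower, and 3576 (926 and 2650) with the isolate as a block. The split was 249 and 712 with median-of-ratios scaling, 303 and 573 with upper-quartile scaling, 279 and 500 with quantile normalization and 98 and 3373 with ribosomal protein scaling. Leaving out single libraries gave 223 genes without control 1, 419 without control 7, 210 without 6 h isolate 1, 298 without 6 h isolate 7, 2136 without 6 h isolate 5 and 848 without 24 h isolate 1. Leaving out whole isolates gave 4 genes without isolate 1, 6595 without isolate 5 and 6 without isolate 7.

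**Figure D1:**
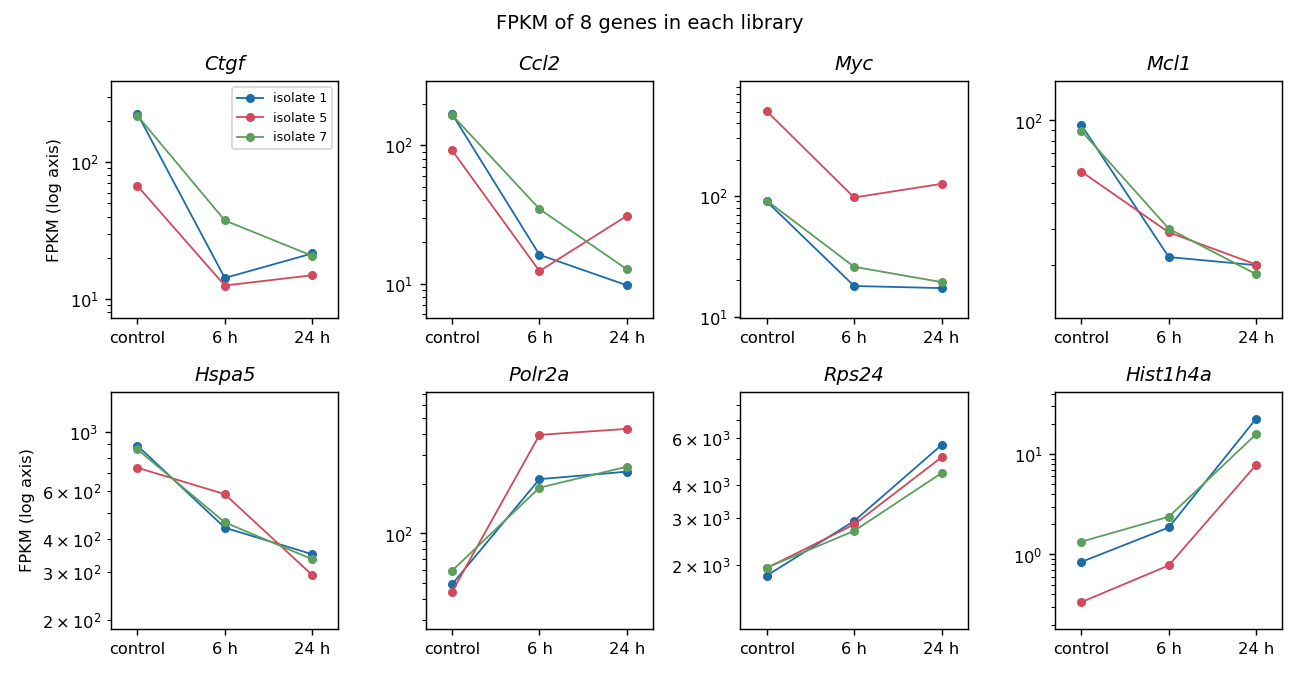
FPKM (log axis) of 8 genes in each of the 9 libraries at control, 6 h and 24 h, with a line per isolate. Ctgf, Ccl2, Mcl1 and Hspa5 were called lower at both times and Polr2a and Rps24 higher at both, Hist1h4a was called higher at 24 h, and the Myc level of isolate 5 lay above those of isolates 1 and 7 in every group.

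The second comparison asked the same of cells after 24 h of triptolide. Thbd, the thrombomodulin gene, fell from 55.2 ± 17.6 to 4.5 ± 1.58 FPKM (log2 change -3.35, adjusted p = 0.000165). Grem1, a secreted antagonist of bone morphogenetic proteins, fell from 134 ± 142 to 10.9 ± 7.06 (adjusted p = 0.0106), with a large spread among controls. The neutrophil chemokine gene Cxcl5 fell from 222 ± 118 to 26.9 ± 8.64 (adjusted p = 0.00417). Ccl2 (-3.05), Gas1 (-3.04), Ankrd1 (-3.02) and Ctgf (-2.92, log2 changes) were again among the 8 largest falls. The pseudogene row Rpl28-ps1 was at 123, 175 and 135 FPKM in control isolates 1, 5 and 7 and listed at 0 in all 24 h libraries. Among activated fibroblast markers, the transcription factor genes Twist1 (31.3 ± 6.47 to 4.67 ± 2.15 FPKM, adjusted p = 0.0015), Prrx1 (23.9 ± 7.21 to 3.74 ± 1.39), Snai2 (log2 change -2.16) and Twist2 (-2.13) fell, 5 of 12 in all and also 5 adjusted over the list alone. The list did not pass camera (adjusted p = 0.789), and its median of -0.62 became 0.02 under upper-quartile scaling, with 3 higher and 3 lower.

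Of the 16 secreted growth factors, 11 fell at 24 h (12 adjusted over the list alone), including Grem1, Nrg1 (to 1.81 ± 0.798 FPKM), the platelet-derived growth factor gene Pdgfc (20.4 ± 1.84 to 2.64 ± 0.271) and Inhba (to 16.2 ± 4.59). The relative median was -1.08. The camera test gave adjusted p = 0.0117 with the preset correlation, and adjusted p = 0.584 with an estimated correlation. In the TGF-beta pathway and targets, 12 of 25 fell and 1 rose, the same counts adjusted over the list alone, including the ubiquitin ligase gene Smurf1 (log2 change -2.47) and Pmepa1 (-2.03). Among cytokines 8 of 21 fell and 1 rose (8 and 1 adjusted over the list alone). Cxcl10 was at 54.7 ± 70.6 and 4.02 ± 0.987 FPKM (adjusted p = 0.0238) and Lif at 28.7 ± 28.3 and 3.63 ± 2.87 (adjusted p = 0.0181). Neither of these lists passed camera at 24 h (adjusted p = 0.317 and 0.742). The gene that rose among the cytokines was Il6, an inflammatory cytokine, from 1.35 ± 0.63 to 6.93 ± 1.78 FPKM (log2 change 1.76, adjusted p = 0.00336).

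Among all 11924 genes 4586 fell at 24 h, and of 28 mitosis genes 11 did (10 adjusted over the list alone; 16 with the isolate as a block; 4 lower and 3 higher with upper-quartile scaling). These included the phosphatase gene Cdc25b (30.1 ± 10.9 to 4.98 ± 0.935 FPKM), Bub3 (60.6 ± 6.68 to 21.5 ± 3.25), the kinase gene Plk1 (32.3 ± 14.8 to 10.5 ± 1.05) and Ttk (log2 change -1.32). Of 28 DNA replication and G1/S genes, 5 fell and 1 rose, the same counts adjusted over the list alone (9 and 1 with the block; 2 lower and 6 higher with upper-quartile scaling). Gins1 (log2 change -1.64) and the cyclin D1 gene Ccnd1 (-1.29) fell and the folate enzyme gene Dhfr rose (1.76). The raw median of DNA replication and G1/S genes was -0.22 and the relative median 0.25, and camera pointed up (adjusted p = 0.798). Of 18 aminoacyl-tRNA synthetases, which charge tRNAs, 12 fell and 1 rose, the same counts adjusted over the list alone and 15 and 2 with the block. Farsa went from 67.1 ± 8.76 to 24.9 ± 3.38 FPKM. Of 16 TFIIH and RNA polymerase II subunits, 11 fell and 2 rose (11 and 3 adjusted over the list alone; 11 and 4 with the block). The TFIIH subunit genes Gtf2h2 (20.5 ± 2.83 to 3.36 ± 0.847 FPKM) and Ccnh (29.9 ± 2.54 to 8.04 ± 0.685) fell, while Polr2a (308 ± 108 FPKM at 24 h) and Polr2l (7.54 ± 1.84 to 28.1 ± 8.25) rose. Of genes that restrain apoptosis, Mcl1 (19.4 ± 1.15 FPKM, log2 change -1.96), Bcl2l1 (-1.19) and Xiap (-1.07) fell, as did the pro-apoptotic Bak1 (29.6 ± 1.68 to 4.76 ± 1.08 FPKM). The anti-apoptotic list held 4 falls and 1 rise among 10 genes and the pro-apoptotic list 6 and 1 among 19 (4 and 1, and 3 and 0, adjusted over the list alone). With the block the pro-apoptotic genes had 10 falls and 3 rises. Neither passed camera (adjusted p = 0.651 and 0.993), and the raw median of the anti-apoptotic genes went from -0.50 to 0.05 under quantile normalization. The camera tests of the mitosis, synthetase, and TFIIH lists gave adjusted p = 0.374, 0.186 and 0.378.

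Most measured replication-dependent histones and cytosolic ribosomal proteins rose at 24 h. Of 21 replication-dependent histones, whose mRNAs normally lack a poly(A) tail, 13 rose and 0 fell, the same counts adjusted over the list alone and 19 and 0 with the isolate as a block. Hist1h4a (chromosome 13, 23760692 to 23761230) rose from 0.84 ± 0.503 to 15.4 ± 7.4 FPKM, Hist1h4d from 0.287 ± 0.256 to 10.7 ± 5.25, Hist2h2bb from 0.37 ± 0.298 to 9.78 ± 1.69 and Hist1h2bp from 0.555 ± 0.467 to 7.93 ± 4.01. These genes are near-identical copies, so the share of each is uncertain. The filter used the mean of all 9 libraries, so members low in the controls could enter through their 24 h values. The counts, the relative median and the camera test of the 21 members therefore lean towards rises. Over all 33 members with a row of their own, the median FPKM was 0.43 in the controls, 0.747 at 6 h and 3.81 at 24 h. The list lay at 2.15 relative to all genes. By camera, adjusted p = 1.60e-09 with the preset correlation, and adjusted p = 0.803 with an estimated correlation. Of 9 replication-independent histones, by limma 0 rose and 2 fell (H1f0 and H3f3b, log2 changes -1.98 and -1.38), the same counts adjusted over the list alone, 2 and 3 at an unadjusted p under 0.05 and 2 and 4 with the block. With upper-quartile scaling 4 replication-independent histones rose and 2 fell, and camera gave adjusted p = 0.926. Of 58 cytosolic ribosomal proteins, 55 rose and 0 fell (57 and 0 adjusted over the list alone), with Rpl37a going from 704 ± 257 to 2312 ± 336 FPKM and Rpl31 from 349 ± 48.9 to 1055 ± 395. Rps27 went from 1196 ± 192 to 3431 ± 711 and Rpl35 from 340.0 ± 21.1 to 961 ± 209. The relative median was 1.61. By camera, adjusted p = 1.41e-29 and adjusted p = 0.584 with an estimated correlation. In cytosolic ribosomal proteins, 13 rose with quantile normalization. Ribosomal protein genes have near-identical pseudogenes, so their levels carry the same uncertainty, and ribosomal protein scaling removes the list's rise by construction (2 higher and 2 lower). The rise is one in the share of the library, and whether the amount per cell rose was not measured.

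Energy, lysosome, redox and matrix genes moved in both directions at 24 h. In nuclear-encoded oxidative phosphorylation, 16 of 64 rose and 5 fell (14 and 4 adjusted over the list alone; 34 and 10 with the isolate as a block). Cox6c rose (251 ± 70.1 to 753 ± 81.1 FPKM), as did Ndufa1 (113 ± 30.2 to 312 ± 103) and Ndufa3 (123 ± 47.6 to 278 ± 50.4), while Ndufs7 fell (57.2 ± 12.3 to 23 ± 3.5). In autophagy and lysosome genes 9 of 21 rose and 5 fell, the same counts adjusted over the list alone and 10 and 8 with the block. The autophagy receptor gene Sqstm1 fell (482 ± 426 to 118 ± 27.7 FPKM) and the lysosomal membrane gene Lamp1 rose (371 ± 32.3 to 974 ± 211). In the oxidative stress response 6 of 24 rose and 1 fell, the same counts adjusted over the list alone and 11 and 5 with the block. They had Sod2 (31.2 ± 3.81 to 53.9 ± 6.73 FPKM) and Sod1 (335 ± 61.5 to 542 ± 47.4) higher and Hmox1 (to 26.1 ± 10.4) lower. In collagens and other extracellular matrix, 6 of 25 rose and 1 fell (5 and 1 adjusted over the list alone; 9 and 5 with the block). The fibulin genes Fbln1 (8.7 ± 4.99 to 22.1 ± 3.21 FPKM) and Fbln2 (219 ± 30.8 to 402 ± 85.5) and the nidogen gene Nid1 rose, and Thbs1, the thrombospondin gene, fell (117 ± 65.4 to 21.3 ± 3.6). Relative medians of the 4 lists were 0.79, 0.86, 0.84 and 0.57 (camera adjusted p = 9.03e-07, 0.0184, 0.00605 and 0.0255). With an estimated correlation, adjusted p = 0.857, 0.857, 0.711 and 0.857. Under ribosomal protein scaling the raw medians of all 4 turned negative (-0.80, -0.70, -0.74 and -0.82). That of collagens and other extracellular matrix did so with protein-coding rows only (-0.08).

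**Figure D2:**
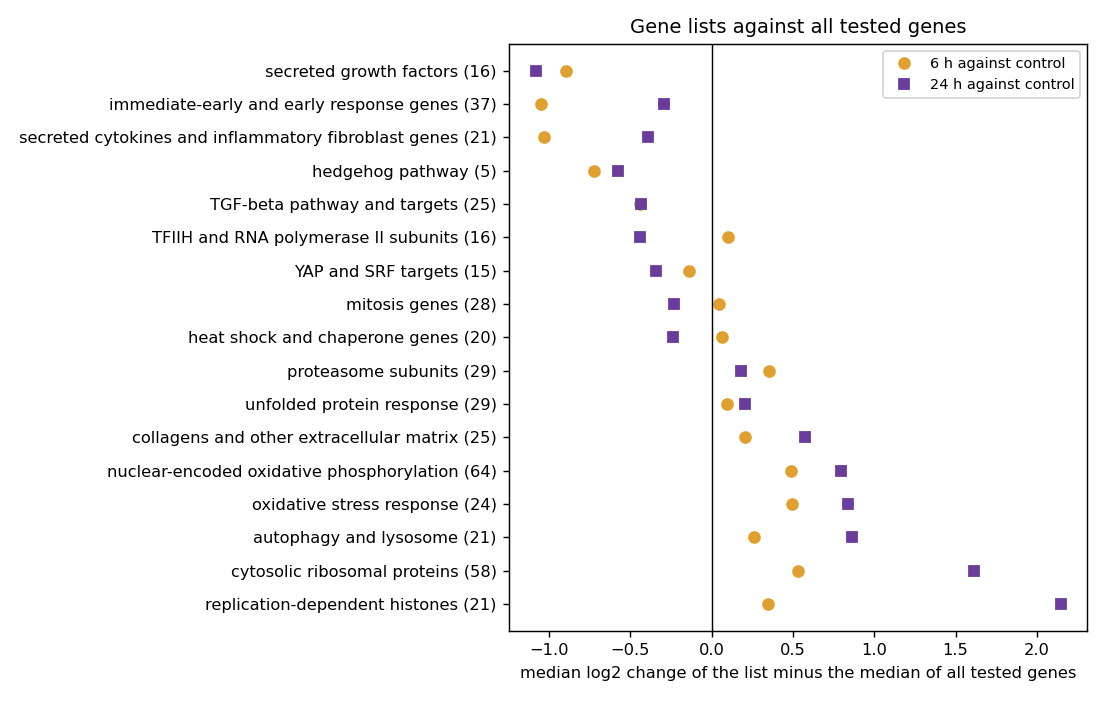
Median log2 change of 17 gene lists minus the median of all tested genes (x axis), with circles for 6 h and squares for 24 h against control and the number of measured genes in parentheses. Replication-dependent histones lay highest at 24 h (2.15) and secreted growth factors lowest (-1.08), and under quantile normalization the relative median turned negative for proteasome subunits at 24 h (-0.27) and for heat shock and chaperone genes at 6 h (-0.07). The measured replication-dependent histones passed the filter in part through their 24 h values.

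Non-coding rows were again among the largest rises at 24 h. Gm20678 rose from 1.05 ± 0.518 to 68.8 ± 44.2 FPKM (log2 change 4.81, adjusted p = 0.000664), Gm15634 from 0.294 ± 0.427 to 27.8 ± 9.55 and AY036118 to 1166 ± 110.5. In isolates 1, 5 and 7 at 24 h, Gm23100 was at 179, 78.5 and 58.2 FPKM, Gm25134 at 25.6, 131 and 15.6, Gm22979 at 18.9, 20.9 and 34.8 and Gm23464 at 19.6, 21.5 and 16.6, and these 4 were listed at 0 in every control library. Gm26141 was at 137, 0 and 0 FPKM in the controls, was listed at 0 at 6 h and was at 261, 149 and 103 at 24 h. Among protein-coding genes, chosen after their values were seen, Alpk2 (chromosome 18, 65265529 to 65394066) rose from 2.49 ± 0.913 to 58.4 ± 6.96 FPKM (adjusted p = 0.00015), Nup210l from 1.32 ± 0.932 to 23.9 ± 2.07, Sag, which encodes a retinal arrestin, from 0.554 ± 0.266 to 17.3 ± 10.2, and Cd79a, a B cell receptor component, from 0.123 ± 0.0942 to 8.42 ± 1.19. Nup210l ends 474 bp from Rps27 (1195.5 FPKM in the controls) and Cd79a 715 bp from Arhgef1, and reads of such neighbours were not separated. Of the keratin genes, also chosen after, Krt18 (to 303 ± 88.4 FPKM) and Krt19 (to 27.4 ± 2.12) fell, and Msln rose to 215 ± 37.2, although its change turned to -0.07 (log2) under ribosomal protein scaling. The marker list of tumour epithelium had 3 falls and 1 rise among 13 genes, the same counts adjusted over the list alone and 5 and 1 with the block (camera adjusted p = 0.789). Kras, the oncogene mutated in these mice and also chosen after, was at 73.9 ± 16.9 FPKM in the controls and 25.9 ± 11.7 at 6 h (adjusted p = 0.0756) and fell to 14 ± 10.3 at 24 h (adjusted p = 0.0029).

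At 24 h limma called 6004 of 11924 genes, 1418 higher and 4586 lower, and 7963 (2050 and 5913) with the isolate as a block. The split was 2207 and 3012 with median-of-ratios scaling, 2704 and 2346 with upper-quartile scaling, 2237 and 2560 with quantile normalization and 287 and 8500 with ribosomal protein scaling, so that upper-quartile scaling turned the majority. Leaving out any single library gave 4647 to 6404 genes, and leaving out an isolate gave 1431 without isolate 1, 9363 without isolate 5 and 2037 without isolate 7.

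**Figure D3:**
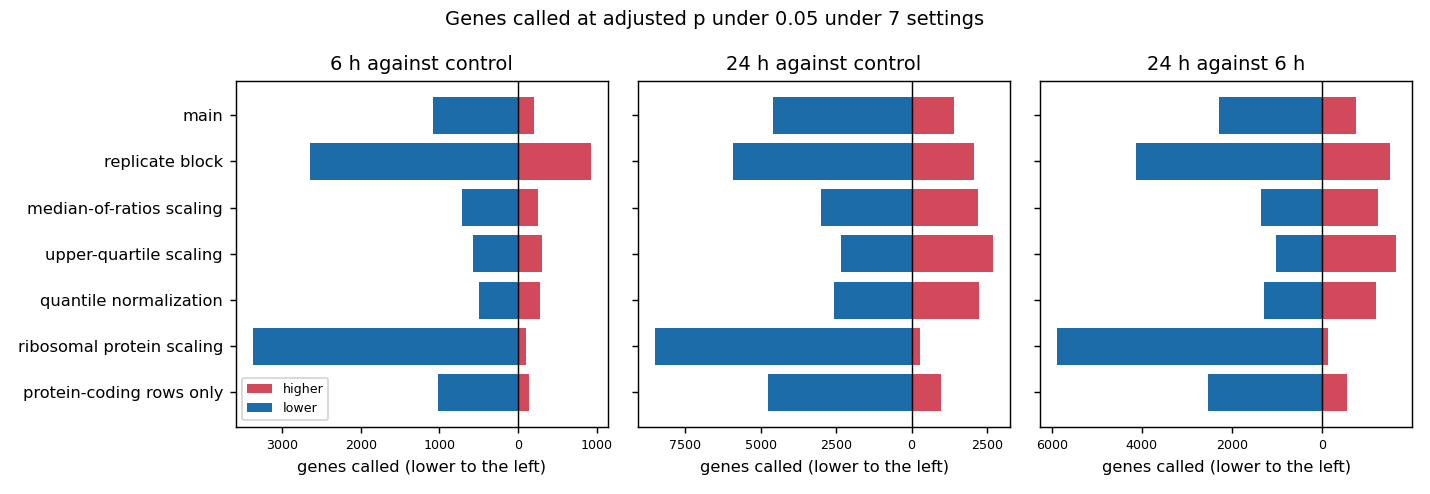
Number of genes called at adjusted p under 0.05 (x axis; higher to the right in red, lower to the left in blue) under 7 settings, for 6 h against control, 24 h against control and 24 h against 6 h. Lower calls outnumbered higher calls in the fit as reported (1083 against 196 at 6 h and 4586 against 1418 at 24 h), while with upper-quartile scaling higher calls outnumbered lower ones at 24 h (2704 against 2346) and at 24 h against 6 h (1623 against 1017).

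The third comparison set 24 h against 6 h. Galk1, the galactokinase gene (chromosome 11, 116008457 to 116012719), fell from 37.6 ± 2.17 to 7.1 ± 2.27 FPKM (log2 change -2.29, adjusted p = 0.00124), and 2010204K13Rik (log2 change -2.26), Ptplad1 (-2.21) and Nsfl1c (-2.16), a cofactor gene of the p97 ATPase, fell as well. Of 29 proteasome subunits, 11 fell and 0 rose (13 and 0 adjusted over the list alone; 22 and 1 with the isolate as a block). Psma7 went from 333 ± 75.9 to 135 ± 53.9 FPKM, Psmd6 from 107 ± 38.1 to 41.3 ± 15 and Psmc6 from 166 ± 12.5 to 67.5 ± 11.1. Of 16 TFIIH and RNA polymerase II subunits, 10 fell and 1 rose, the same counts adjusted over the list alone, including Gtf2h2 (log2 change -1.47), Polr2j (61.2 ± 5.52 to 24.1 ± 5.0 FPKM), Polr2i (-1.31) and Mnat1 (-1.29). Relative medians were -0.33 for the proteasome (camera adjusted p = 0.00233; adjusted p = 0.857 with an estimated correlation) and -0.44 for the TFIIH and polymerase list (camera adjusted p = 0.0232, or 0.135 with the block; adjusted p = 0.584 with an estimated correlation).

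Some early response genes were higher at 24 h than at 6 h. Against control at 24 h, 19 of the 37 measured were lower and 6 higher (19 and 7 adjusted over the list alone; 25 and 9 with the isolate as a block). That list's relative median against control was then -0.30, and it did not pass camera (adjusted p = 0.585). Of the 37 immediate-early and early response genes, 7 rose between 6 h and 24 h and 0 fell, against 0 adjusted over the list alone by limma, 13 higher at an unadjusted p under 0.05 and 16 higher and 2 lower with the isolate as a block. Atf3, a stress-induced transcription factor gene, rose from 8.09 ± 2.93 to 34.8 ± 7.61 FPKM (adjusted p = 0.0353), the growth arrest gene Gadd45b from 17.1 ± 2.53 to 43.7 ± 6.56, the nuclear receptor gene Nr4a2 from 6.33 ± 0.542 to 14.7 ± 5.44 and Klf4 from 3.81 ± 0.988 to 8.03 ± 2.12. The relative median was 0.68 (camera adjusted p = 1.70e-05; adjusted p = 0.584 with an estimated correlation). With ribosomal protein scaling the raw median of immediate-early and early response genes turned to -0.20, with 0 higher and 7 lower. Between 6 h and 24 h, limma called 10 of 21 replication-dependent histones higher (12 adjusted over the list alone; 20 with the block). These 21 members passed the filter in part through their 24 h values. Of the 9 replication-independent histones it called 0 higher and 0 lower (0 and 4 at an unadjusted p under 0.05; 1 and 4 with the block). Higher calls were also made for 36 of 58 cytosolic ribosomal proteins (44 adjusted over the list alone; 58 with the block), with Hist1h4c at a log2 change of 1.92 and Rps24 at 0.84. The relative medians of the replication-dependent histones and ribosomal proteins were 1.65 and 1.01 (camera adjusted p = 1.27e-10 and 1.78e-25; adjusted p = 0.777 and 0.584 with an estimated correlation). In autophagy and lysosome, 6 of 21 rose and 2 fell (7 and 2 adjusted over the list alone; 10 and 4 with the block), Atg14 and Lamp1 (log2 changes 1.28 and 1.04) against Atg4b (-1.15) and Atg5 (-1.03). That list's relative median was 0.48 (camera adjusted p = 0.031; adjusted p = 0.857 with an estimated correlation). Its raw median was -0.44 under ribosomal protein scaling.

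Between 6 h and 24 h limma called 3034 genes, 748 higher and 2286 lower, and 5613 (1493 and 4120) with the isolate as a block. The split was 1234 and 1365 with median-of-ratios scaling, 1623 and 1017 with upper-quartile scaling, 1187 and 1291 with quantile normalization and 127 and 5878 with ribosomal protein scaling. The largest rises included BC051077 (1.38 ± 0.734 to 22.7 ± 13.5 FPKM) and Gm20678 (log2 change 3.53), besides Gm26141, Gm23464 and Gm22979, and Gm25190 went from 644, 2016 and 699 FPKM to being listed at 0. Leaving out 6 h isolate 1 gave 1984 genes, 6 h isolate 7 gave 1602 and 24 h isolate 1 gave 1489. Leaving out isolate 1, 5 or 7 altogether gave 18, 7604 and 9 genes.

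The calls at 6 h and 24 h were compared with each other. Of the 1279 genes called at 6 h, 1171 were called in the same direction at 24 h (185 rose and 986 fell), against 23.3 and 417 expected of independent lists. That expectation leaves out the shared controls, and with 3 controls the comparisons could not each be given 2 of their own, so part of the excess may come from the shared controls. In 100 simulations of unchanged groups against the same controls the mean was 0, a value that calls on unchanged groups can hardly exceed. The circadian repressor gene Cry2 (6.03, 2.95 and 10.98 FPKM in control, 6 h and 24 h cells), Frat2 (6.11, 3.20 and 10.7) and Thap1 (11.2, 4.96 and 27.3) were the 3 genes called lower at 6 h and higher at 24 h. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.667 and a covariance of 0.464, against 0.498 and 0.138 in the simulations, a difference in covariance of 0.325. Those simulations left out the pairing by isolate, and with the isolate effects kept, a simulation added after the data had been seen, the values were 0.4997 and 0.092, a difference in covariance of 0.372. Of the 1083 genes that fell at 6 h, 288 were lower still at 24 h, 52 were higher and 743 were not distinguished between the times. A further 3600 genes fell and 1230 rose at 24 h without a call at 6 h.

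**Figure D4:**
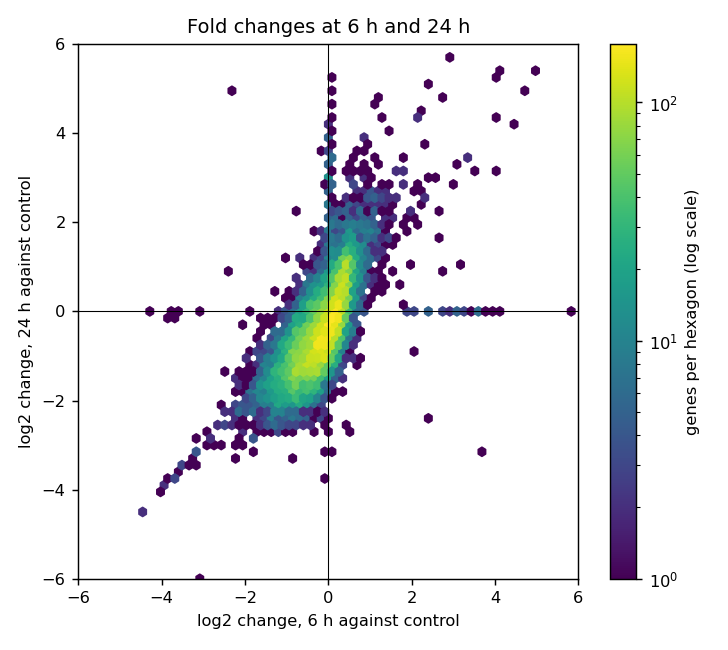
Log2 change at 24 h against control (y axis) plotted against that at 6 h (x axis) for the tested genes, as hexagons coloured by the number of genes on a log scale, with both axes limited to 6 in either direction. Most genes lie along a rising diagonal (Pearson r = 0.667, against 0.498 for simulated unchanged groups), and hexagons along the vertical and horizontal zero lines hold rows with a change near 0 at one of the times.

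The remaining genes fixed in advance covered known targets, stress and reference genes. Myc, a short-lived oncogene transcript, measured 90.1, 504 and 91.7 FPKM in control isolates 1, 5 and 7, 18, 97.1 and 25.9 at 6 h and 17.3, 126 and 19.4 at 24 h. Limma did not call it (adjusted p = 0.208 and 0.0992) but did with the isolate as a block (0.000999 and 6.62e-05). Fos was at 82.7 ± 58.9 and 16.7 ± 7.12 FPKM (adjusted p = 0.0763, 0.0174 with the block) and fell to 14.3 ± 0.61 at 24 h. Mdm2, the p53 ubiquitin ligase gene, fell from 21.9 ± 8.94 to 7.2 ± 2.74 FPKM at 6 h and was at 11.8 ± 2.07 at 24 h (adjusted p = 0.0683, 0.0415 with the block). Hspa5 fell from 827 ± 81.6 to 495 ± 79 and 326 ± 29.6 FPKM, and Il6 was the only fixed signalling gene called higher at 24 h. Ercc3, the gene of the triptolide target, was at 23.9 ± 8.67, 30.8 ± 8.11 and 37.6 ± 12.7 FPKM (adjusted p = 0.559 and 0.181, or 0.0334 and 0.00152 with the block). The row shared by Acbd4 and Hexim1, an inhibitor of the elongation factor P-TEFb, was at 15.3 ± 1.03 and 26.9 ± 8.54 FPKM (adjusted p = 0.055, 0.0222 with the block) and rose to 33.4 ± 1.19 at 24 h.

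Several fixed genes were not called by limma without the block. The stress gene Ddit3 was at 29 ± 26.6, 20.7 ± 13.5 and 56.4 ± 11.4 FPKM (adjusted p = 0.109 at 24 h, 0.0477 with the block; 0.0906 and 0.0327 at 24 h against 6 h). Its log2 change at 24 h was 2.304, -0.41 and 1.92 in isolates 1, 5 and 7. Cxcl12 was at 17.1 ± 13.4, 11.5 ± 8.28 and 7.49 ± 5.35 (adjusted p = 0.544 at 24 h, 0.00694 with the block). Cxcl1 was at 119 ± 65.5, 38.6 ± 22.6 and 68.8 ± 29.4 (adjusted p = 0.154 at 6 h, 0.0739 with the block). Its log2 change at 6 h was -1.71, -1.75 and -1.46 in isolates 1, 5 and 7. Tgfb1 (39.3 ± 4.64, 35 ± 2.1 and 44.4 ± 17 FPKM), Fn1 (349 ± 237, 373 ± 242 and 376 ± 298) and Acta2 (53 ± 45.2, 50.5 ± 43.4 and 47.5 ± 38.8) were not distinguished, nor was the row shared by the heat shock genes Hspa1a and Hspa1b (14.6 ± 10.4, 21.5 ± 4.25 and 21 ± 8.28). The row shared by Ap1s1 and Serpine1 was at 152 ± 54.4, 185 ± 61.4 and 168 ± 61.1 FPKM (adjusted p = 0.722 at 6 h, 0.0392 with the block), and Gli1, like Col1a1 and Fap, lay below the filter (0.0788 ± 0.0323 FPKM in the controls). Of the reference genes, Gapdh was at 1862 ± 157 and 2564 ± 259.8 FPKM (adjusted p = 0.129, 0.0156 with the block) and rose to 3522 ± 617 at 24 h (log2 change 0.91). Gapdh turned to -0.09 under quantile normalization and -0.22 under ribosomal protein scaling. Actb was at 1585 ± 536, 1346 ± 561 and 851 ± 409 FPKM (adjusted p = 0.145 at 24 h, 0.000396 with the block).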

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

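The counts of splits in this part were planned, while the genes named here were picked by their values. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each of the 3 comparisons 1 of the 10 splits, the real one, gave as many genes: 1279 at 6 h against at most 2 in another split, 6004 at 24 h against at most 1, and 3034 at 24 h against 6 h against at most 2.

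The times differed in several places. The 6 h and 24 h levels of 3034 genes differed by limma. Cry2, Frat2 and Thap1 were called lower at 6 h and higher at 24 h, with log2 changes between the times of 1.59, 1.48 and 2.19 (SE 0.182, 0.168 and 0.255, n = 3 libraries per group), each higher at 24 h in all 3 isolates. Against control at 24 h their log2 changes were 0.75, 0.72 and 1.15. None exceeded the raw median of the cytosolic ribosomal proteins (1.15), so their direction against control can depend on the scaling. Of the immediate-early and early response genes, 7 were called higher at 24 h than at 6 h.

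Isolates went in opposite directions for Cxcl1, a neutrophil chemokine gene: at 24 h its log2 change was 1.18 in isolate 5 but -1.52 in isolate 1 and -1.62 in isolate 7, a difference that was not tested. Rows without a gene name, which entered no comparison, held 3.58% of the FPKM sum at 6 h and 4.65% at 24 h, against 3.19% in the controls.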

How the results depend on the processing

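The alternatives that use protein-coding rows only, keep rows sharing a symbol apart, leave out rows listed at 0, or block isolates 1 and 7 alone were chosen after the data had been seen. The number of genes called at 24 h held within 1.5 times under the pseudocounts, filters, moderation settings and 2-group fit. Falls stayed the majority of these calls, but without a filter only narrowly (4490 lower and 4026 higher). Where no cause is given below, the cause was not tested. Without a filter, 823 genes were called at 6 h, the shares that fell were 79.34%, 52.72% and 48.59% (6 h, 24 h, 24 h against 6 h), 761 genes were shared in direction by both times and 40 list tests passed; more low rows were then tested. With a mean of at least 5 FPKM the shares were 90.14%, 80.48% and 81.71%. A pseudocount of 0.1 gave 81.86% at 6 h and 77.87% at 24 h against 6 h. Under median-of-ratios scaling the shares were 74.09%, 57.71% and 52.52%. Under upper-quartile scaling they were 65.41%, 46.46% and 38.52%, with an overlap of 747. Under quantile normalization 779 genes were called at 6 h, the shares were 64.18%, 53.37% and 52.1%, and the overlap was 666. Ribosomal protein scaling gave 3471 genes at 6 h and 6005 at 24 h against 6 h, shares of 97.18%, 96.73% and 97.89% and an overlap of 3416, since it raises the controls against the treated libraries by construction.

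The replicate block gave 3576 genes at 6 h, 5613 at 24 h against 6 h, shares of 74.11% at 6 h and 74.26% at 24 h and an overlap of 3193; of the named genes it strengthened 24 calls and ended 0, of the described lists it ended 1, and it changed no other call. The block with median-of-ratios scaling gave 3654 and 5177 genes, shares of 58.84%, 57.72% and 54.14% and an overlap of 3029. The block on isolates 1 and 7 only gave 6107, 9175 and 7247 genes, shares of 72.52%, 73.23% and 68.03% and an overlap of 5123. Fitting 2 groups only gave 820 genes at 6 h and shares of 78.78% and 77.08% (6 h and 24 h). Protein-coding rows only gave shares of 87.63%, 82.88% and 82.43% and a correlation of the 6 h and 24 h changes of 0.7492, and without rows listed at 0 that correlation was 0.7364.

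Leaving out a library or isolate gave 4 to 6595 genes at 6 h, 1431 to 9363 at 24 h and 9 to 7604 at 24 h against 6 h, with the lowest counts without isolate 1 (6 h and 24 h) or 7 and the highest without isolate 5. The shares that fell ranged over 0 to 89.2%, 73.17% to 77.27% and 33.33% to 78.38%, the overlap over 1 to 5488 (218 without control 1, 400 without control 7, 208 without 6 h isolate 1, 289 without 6 h isolate 7, 1908 without 6 h isolate 5 and 776 without 24 h isolate 1), the correlation over 0.6123 to 0.7019 and the list tests passed over 23 to 28. Of 337 values tracked for named genes, the call of 201 ended without isolate 1, 196 without isolate 7 and 3 without isolate 5.

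Besides those given with the comparisons, some values changed sign (log2). Under ribosomal protein scaling they included Tgfb1 (-0.99), Gapdh (-0.22), Fbln2 (-0.26), Nid1 (-0.26), Bag1 (-0.39), Fth1 (-0.073), Sod2 (-0.33) and Sod1 (-0.42) at 24 h and Ltbp3 (-0.16), Axl (-0.71) and Fth1 (-0.18) at 24 h against 6 h. Under quantile normalization they included Gapdh (-0.091) and Fth1 (-0.046) at 24 h and Fth1 (-0.10) at 24 h against 6 h. Without control isolate 5 the median of the mitosis genes at 6 h was -0.255 relative to all genes, within leave-out values of -0.255 to 0.211. Without isolate 5, Cdk1 was at -0.24 at 6 h (up to 0.185 without isolate 1) and the row HSPA1A,HSPA1B at 0.41 at 24 h against 6 h, and with the block on isolates 1 and 7 only Acta2 was at -0.18 at 24 h and HSPA1A,HSPA1B at 0.41. Absolute depth is unknown, so the limit it sets on rows at or near 0 cannot be stated.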

Other observations

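The tests of depth, of an even background, of transcription running on from neighbours and of less messenger RNA against other RNA were chosen after the result was seen; those of gene length, abundance and the FPKM scale were written before. Isolate 5 differed from the others in single genes, picked here by their values and not tested as groups. In control isolates 1, 5 and 7, Isg15, an interferon-induced ubiquitin-like gene, measured 8.56, 204 and 10.4 FPKM, Usp18, which removes it from proteins, 0.626, 64.6 and 0.842, Ifi44 0.443, 67.9 and 0.306 and the chemokine gene Ccl5 4.16, 73.6 and 6.12. Over the 3 groups, isolate 5 was higher than isolate 1 for Usp18 (log2 difference 4.68, adjusted p = 0.000519 by limma), the interferon regulatory factor gene Irf7 (2.94, adjusted p = 0.00315) and Ifit1 (3.64, adjusted p = 0.000291), and lower for Bgn (-7.27, adjusted p = 2.57e-05), the versican gene Vcan (-2.88) and Tff1 (-3.21), while the fibronectin gene Fn1 measured 218, 623 and 207 FPKM in control isolates 1, 5 and 7. Each isolate is 1 preparation, so the p-values between isolates do not measure the spread between preparations. The 22 interferon-stimulated genes had a median log2 change of -0.94 at 24 h, with 1 called higher and 1 lower (0 and 0 adjusted over the list alone by limma, 1 and 2 at an unadjusted p under 0.05) and 1 and 10 with the block. Their camera test pointed up, against the sign of the median (adjusted p = 0.689).

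Other lists held called members at 24 h without passing camera. All 5 measured genes of the hedgehog pathway fell (also 5 adjusted over the list alone), including Sufu (log2 change -1.03), with camera adjusted p = 0.0982. Of 188 zinc finger genes 96 fell and 9 rose (98 and 9 adjusted over the list alone; camera adjusted p = 0.0612). Of 29 genes of the unfolded protein response 8 fell and 6 rose, the same counts adjusted over the list alone, with the transcription factor gene Xbp1 going from 78.1 ± 54.5 to 9.67 ± 6.22 FPKM and Trib3 lower by a log2 change of -2.74 (camera adjusted p = 0.476). In the heat shock and chaperone genes 6 of 20 fell and 1 rose (5 and 1 adjusted over the list alone; 11 and 1 with the block; camera adjusted p = 0.876), with Hsf2 at -1.86 and Hsp90aa1 at 1.35 (log2). Pecam1, an endothelial marker gene picked by its values, was at 0.141 ± 0.0442 FPKM in the controls and 4.75 ± 0.875 at 24 h, while Cdh5, a further endothelial marker, was at 0.0368 ± 0.029 and 0.0391 ± 0.00997.

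Genes silent in the controls were detected more often after triptolide: of 1083 olfactory receptor genes, which fibroblasts are not known to use, 1.82% ± 0.586 were above 0 in the controls, 4.31% ± 0.324 at 6 h and 7.79% ± 1.25 at 24 h (SD, n = 3). If the libraries were not rescaled, deeper sequencing is argued against as the cause by a mean relative depth at 24 h of 1.11 times that of the controls. That depth was read from the FPKM values themselves. With rescaling, which the sources used here do not settle, it need not follow the number of fragments. An even background over all silent genes as the whole cause is argued against: of 1028 other protein-coding genes listed at 0 in every control and at least as long as the median olfactory receptor transcript, 8.95% gained more at 24 h than the 99th percentile of the olfactory receptor genes listed at 0 in the controls (0.105 FPKM), against 1.05% of those 1043 (Fisher's exact test, two-sided p = 3.16e-18), and a background under part of the gain stays open. The 1.05% was fixed by the choice of the cut. The p-value takes it as observed and genes as independent, so only the 8.95% carries the comparison. Earlier versions of this test were replaced because they ran on filtered genes or on genes already called higher (58.8% of 1923 above 0.302 FPKM), and a further version gave 28.9% of 6651 silent genes called higher against 10.5% of 191 olfactory receptor genes, a ratio of 2.76. Transcription running on from an expressed neighbour may account for part of it, as 8.84% of the genes called higher lay within 10 kb downstream of an expressed gene on their strand against 3.38% of the others (ratio 2.61, Fisher's exact test, two-sided p = 9.33e-19), a test also redefined after a first version on filtered genes. Yet divergent (2.46), upstream (1.60) and overlapping (1.52) positions were enriched too, and held 5.77%, 6.45% and 5.93% of the genes called higher. Convergent neighbours, on the opposite strand with their 3' end facing that of the gene, were not counted. The share of genes near any expressed neighbour is therefore not known, and other causes remain open.

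The median of the cytosolic ribosomal proteins lay 1.61 (log2) above that of all genes at 24 h (camera adjusted p = 0.584 with an estimated correlation). Gene length as the whole cause is argued against, since the list's median lay 1.57 (log2) above that of 924 protein-coding genes of the same length. Abundance in the controls is argued against in the same way at 24 h, by 0.960 above 142 genes, although their median control FPKM was 429 against 952 for the list and the match is imperfect. At 6 h the list's median of 0.424 lay only 0.137 above the 0.287 of those genes, so abundance is not argued against there. The scale itself depends on the list, as under ribosomal protein scaling 3471 genes were called at 6 h, and no biological explanation was tested.

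Rows of a ribosomal RNA locus and of microRNA precursors were higher after triptolide: AY036118 lies within the annotated ribosomal RNA CT010467.1 (chromosome 17, 39846353 to 39848827), and Mmu-mir-6236, Mmu-mir-6240, Gm15564 and the row of Gm26917 and Gm26924 were called higher as well. All 5 rows were still called higher at 24 h after ribosomal protein scaling, so the shift of that list does not account for their rise. Before that scaling they rose by log2 changes of 2.2 to 4.34, against a raw median of 1.15 for the list. The outcome was therefore nearly given. A loss of messenger RNA that includes the ribosomal protein genes would not be removed by this scaling, so the test cannot decide on the FPKM scale as a whole. Less messenger RNA against RNA of polymerases I and III and of mitochondria may contribute and cannot be told apart from other causes, since 2 of 6 other such rows were called higher (Rn7sk and the row of mt-Cytb and mt-Tt) and 0 lower by limma, and Rpph1 was at 23.4 ± 18.4 and 5.31 ± 2.83 FPKM. Those 6 rows were a selection. Outside it, the merged row of mt-Co1 and other mitochondrial genes was at 26861 ± 8335 FPKM in the controls and 46008 ± 9292.5 at 6 h. The row of mt-Nd6 and mt-Te was at 666 ± 271 and 1140 ± 378. Both were listed at 0 in all 24 h libraries, which can be a failed estimate. Whether these rows carry fragments of ribosomal RNA was not tested.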
